A study of Arabidopsis thaliana with 30 samples.

How the data were processed

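Gene expression was measured in roots of 1-week-old Arabidopsis thaliana seedlings of the accession Col-0 with 30 single-colour oligonucleotide arrays. Seedlings had been treated for 2 h with the main natural auxin, IAA, at 5 µM, or with solvent alone (mock). Cells of 4 root tissues that carried a fluorescent reporter were released by 1 h of cell wall digestion and sorted by fluorescence: the stele, the xylem-pole pericycle, the epidermis together with the lateral root cap, and the columella. Undigested roots were profiled beside them. Each of the 5 sample types had 3 mock and 3 auxin arrays, 10 groups in all, taken from the sample titles. Per the series' design text, digestion of the auxin-treated roots was carried out in medium that still held 5 µM IAA, so sorted cells and intact roots differed in the length of exposure as well as in digestion and sorting, and neither was tested apart from the other. The labels do not say which samples came from separate cultures, so p-values here measure the spread between these samples, which may be in part technical.

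Per the labels, RNA was amplified and biotin-labelled from small amounts before hybridisation. The authors deposited 1 intensity (signal on a linear scale) for each of 22810 probe sets and array, made with MAS5 per the submitters' processing notes; the version, the chip definition and the genome build are not given in the sources used here. The deposited values had been scaled array by array: after the lowest and highest 2% of probe sets were left out, the mean was 250.0 on every array, and no further normalization between arrays was visible in the values. Array medians ran from 54.4 to 82.9. Arrays of a group correlated with r between 0.938 and 0.982 (Pearson, log2 scale, across genes, which are not independent replicates). For arrays, the number of replicates limits the precision; 3 per group were at hand.

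Probe sets were named through the platform annotation provided with the values, which pairs 13513 probe sets with 1 gene, pairs 503 with several genes and does not list 8730; 64 control probe sets were left out. Of the probe sets with 1 gene, 13436 had a gene number found in the RefSeq gene table of the assembly TAIR10.1, which was used only for names and for which genes are neighbours; no coordinates are given because no build is stated for the arrays. A gene was measured by its probe set of highest mean log2 signal among probe sets with 1 gene. Genes were tested if the signal lay above the 40th percentile of its array in at least 3 of 30 arrays, which left 9323 of 13356 genes. Many familiar auxin genes are on probe sets that are unnamed here: of 394 genes in the lists below, 57 were named.

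Signals were analysed as log2(signal + 16). A fold change on this scale understates the change of genes with low signal. Values of all 30 arrays were fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 10 groups and empirical Bayes moderation with an intensity trend; the fit had 20 residual degrees of freedom and a median residual SD of 0.35 (log2). Contrasts gave the auxin response (auxin minus mock) in each of the 5 sample types, the average response of the 4 sorted tissues, the response of intact roots minus that average, and the average mock level of the sorted tissues minus the mock level of intact roots. A moderated F-test with 3 numerator degrees of freedom asked whether the response, or the mock level, differed among the 4 sorted tissues; for genes past it, each tissue was then compared with the mean of the other 3. P-values were adjusted by the Benjamini-Hochberg method over the 9323 genes (over the genes past the F-test for the follow-up comparisons), and a gene was called at an adjusted p under 0.05. All tests were two-sided. The ± after a log2 change is the standard error from this fit, and the ± after a signal is the SD of 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

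The groups, the tests, the gene lists, the rule for naming genes and nearly all alternatives were fixed before the data were examined. For each auxin response the text names genes from the 6 largest rises and 4 largest falls among called genes whose auxin arrays all lay beyond all mock arrays; for the average response from the 12 largest rises and 8 largest falls of one sign in all tissues; for differences between tissues from the 12 smallest F-test p-values and, per tissue, the 5 largest differences each way; for intact against sorted samples from the 8 largest each way; for mock tissues from the 5 largest per tissue; and for each list up to 4 called members and up to 2 others. The 23 fixed lists covered Aux/IAA repressors, GH3 auxin conjugation, SAUR, lateral root initiation, HD-ZIP II, auxin transport, auxin receptors and ARFs, auxin synthesis and breakdown, ethylene, cytokinin, gibberellin and brassinosteroid metabolism, expansins and xyloglucan endotransglucosylases, cell cycle, root stem cell and meristem, root hair, markers of the stele, the pericycle, the epidermis, the root cap and columella, and the endodermis and cortex, light harvesting, wound and jasmonate, and heat shock. Lists with 5 or more tested members were compared with all other genes by camera (limma) with a preset correlation between genes of 0.01 and again with an estimated one; 3 of the fixed lists qualified. Class III peroxidases, AAA-type ATPases of the AATP1 group, photosynthesis genes and 26 families of genes with a shared symbol stem were added after seeing the values. Over the 16 contrasts of each list, 19 of 48 tests of fixed lists passed with the preset correlation and 13 with the estimated one; for the added lists 31 and 9 of 48 passed, and for the families 25 and 0 of 416.

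Simulated data gave every group each gene's real mean in the mock-treated stele, with independent noise of its real spread. Real differences between groups were left out. The fit was tested on these data, in which 200 of 9323 genes were changed. For the response of the stele it recovered 46.1% of genes changed 2-fold and 97.8% of those changed 4-fold; for the average response it recovered 98.1% at 2-fold, and for the F-test of tissue dependence 4.90% at 2-fold and 87.6% at 4-fold. For intact minus sorted it recovered 28.1% at 2-fold, and for mock sorted minus intact 74.0%. Of 400 simulated lists of 10 unchanged genes, 20 passed camera at the unadjusted level of 0.05, and all 400 lists raised 2-fold passed. As genes were simulated independently, this does not show how camera with the preset correlation behaves on lists of correlated genes. Alternatives covered quantile normalization, centring on the 75th percentile, other pseudocounts, other filters, the replicate number as a block, fits limited to the groups compared, array weights, eBayes without a trend, a linear model without moderation, another way to summarise a gene, and leaving out each array in turn. The use of all probe sets and a fit without the 2 arrays of lowest weight were added after seeing the data.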

Results

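The arrays profiled how 4 cell populations of the Arabidopsis root, and the root as a whole, respond to 2 h of auxin. Mock-treated and auxin-treated samples of the stele (the central vascular cylinder), the xylem-pole pericycle (the layer from which lateral roots arise), the epidermis with the lateral root cap, the columella (the central root cap) and undigested roots were each measured on 3 arrays per treatment, 30 in all. In every group the values given are means of 3 arrays. A principal component analysis put 43.2% of the variance between arrays on its first component and 16.4% on the second.

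Which genes respond to auxin across the root was asked with the average response of the 4 sorted tissues. The strongest rise was that of GH3.3 (AT2G23170), which encodes an enzyme that conjugates auxin to amino acids: its signal went from 38.8 ± 16.8 to 9826 ± 1486 in the pericycle (SD, n = 3), and its average change was 6.97 ± 0.11 on the log2 scale (126-fold, adjusted p = 4.52e-34). IAA29 (AT4G32280) and IAA30 (AT3G62100), members of the Aux/IAA family of auxin-response repressors, rose by 6.06 ± 0.15 and 4.34 ± 0.13, and GH3.5 (AT4G27260) rose by 4.94 ± 0.10. AT2G17680, AT1G60010, AT3G26470, AT3G60650, AT5G47440 and AT5G62280, genes without a symbol here, rose by between 3.16 and 3.75. The neighbouring genes AT4G35200 and AT4G35210 rose by 3.09 and 3.04. The largest fall of a named gene was that of AT2G41810, by 4.78 ± 0.14 (27.5-fold, adjusted p = 4.09e-26). AT2G43890, a predicted polygalacturonase, fell by 3.74 ± 0.16, and the glutathione S-transferase gene GSTU28 (AT1G53680) fell by 3.24 ± 0.18. In total 3838 of 9323 genes were called (limma, adjusted p under 0.05), 2326 higher and 1512 lower (1841 and 1703 with quantile normalization), of which 194 rose and 243 fell more than 2-fold.

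**Figure D1:**
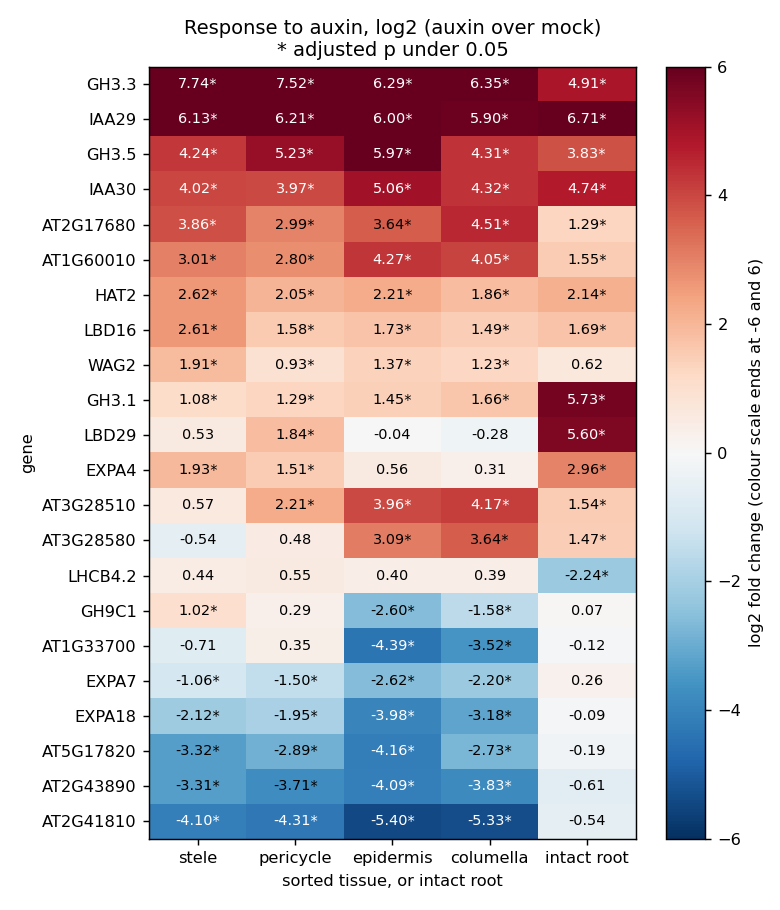
Response to auxin (log2, auxin over mock) of 22 genes in the 4 sorted tissues and intact roots; asterisks mark an adjusted p under 0.05. IAA29 rose by between 5.90 and 6.71 in all 5 columns, while GH3.1 rose by 1.08 in the stele and 5.73 in intact roots.

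Of the fixed lists, the Aux/IAA repressors and the GH3 enzymes rose. Of 6 tested Aux/IAA genes, 5 rose on average and none fell, and 5 rose when adjusted over the list alone; the list's mean change was 2.16 (camera adjusted p = 1.52e-05, and adjusted p = 0.0116 with an estimated correlation). Of 5 tested GH3 genes, 4 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 2.83e-06, and adjusted p = 5.56e-04 with an estimated correlation). The gene that fell was GH3.17 (AT1G28130), at −0.31 ± 0.11. Both lists were also called in each of the 4 tissues and in intact roots, with the preset and with the estimated correlation. The single members tested of the HD-ZIP II, auxin transport and ethylene lists were called on average: the homeobox gene HAT2 (AT5G47370) rose by 2.18 ± 0.11, the kinase gene WAG2 (AT3G14370), a regulator of auxin efflux carriers, by 1.36 ± 0.13, and RTE1 (AT2G26070), a regulator of an ethylene receptor, by 1.29 ± 0.17. Among 4 lateral root initiation genes, LBD16 (AT2G42430) rose in every tissue and by 1.85 ± 0.14 on average, and PUCHI (AT5G18560) rose by 1.09 ± 0.18 on average; 3 of the 4 rose, and 4 when adjusted over the list alone. Of 4 genes of auxin synthesis and breakdown, DAO1 (AT1G14130), an auxin oxidase gene, was the only gene called on average, also when adjusted over the list alone, and fell by 0.49 ± 0.14. The lists of SAUR genes, auxin receptors and ARFs, cytokinin genes, gibberellin and brassinosteroid metabolism, and pericycle markers had no tested member.

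Cell wall genes moved both ways. Of 10 expansins and xyloglucan endotransglucosylases, 5 fell and 1 rose on average, with the same counts when adjusted over the list alone (camera adjusted p = 0.0397, but adjusted p = 0.182 with an estimated correlation). The expansins EXPA18 (AT1G62980) and EXPA7 (AT1G12560), which act in root hair growth, fell by 2.81 ± 0.18 and 1.84 ± 0.17, and EXPB1 (AT2G20750) fell by 1.89 ± 0.16, while EXPA4 (AT2G39700) rose by 1.08 ± 0.17. All 3 tested members of the root hair list fell on average, also when adjusted over the list alone, though the call for XTH26 was lost in 4 settings. The class III peroxidases AT5G17820, AT4G26010 and AT2G18980 fell by 3.27 ± 0.28, 2.75 ± 0.18 and 2.68 ± 0.16. A list of 42 tested class III peroxidases, written after these values were seen, held 11 that fell and 9 that rose, and 12 that fell and 9 that rose when adjusted over the list alone (camera adjusted p = 0.0394, but adjusted p = 0.258 with an estimated correlation).

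In the stele 2270 genes were called, 1324 higher and 946 lower (1146 and 1180 with quantile normalization), the largest count of the 5 responses. GH3.3 rose by 7.74 ± 0.23, IAA29 by 6.13 ± 0.29 and IAA30 by 4.02 ± 0.27. PUCHI, an AP2-type regulator of lateral root initiation, rose by 2.32 ± 0.35 (adjusted p = 9.11e-06) and LBD16 by 2.61 ± 0.28; 2 of the 4 lateral root initiation genes rose, the same number when adjusted over the list alone. EXPA4 rose by 1.93 ± 0.34. The DNA replication gene MCM7 (AT4G02060), the cell cycle gene tested, rose by 1.02 ± 0.31 in the stele (not called without stele control replicate 3 or stele auxin replicate 1). Of 2 root stem cell and meristem genes BBM (AT5G17430) was called higher, at 1.28 ± 0.41, a call lost without moderation and when any of 4 stele arrays was left out. Both lists had the same counts when adjusted over the list alone. The largest falls were those of AT2G41810 (17.1-fold), AT1G28160, which encodes an AP2/ERF-type protein, by 3.43 ± 0.34, AT5G17820, by 3.32 ± 0.55, and AT2G43890, by 3.31 ± 0.32. The count was lower when single arrays were left out: 1448 without stele auxin replicate 2 and 1508 without stele control replicate 1.

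In the pericycle 1143 genes were called, 612 higher and 531 lower (547 and 675 with quantile normalization, 556 and 569 with centring on the 75th percentile). GH3.3, IAA29 and GH3.5 rose by 7.52 ± 0.23, 6.21 ± 0.29 and 5.23 ± 0.21. LBD29 (AT3G58190), a transcription factor of lateral root initiation, rose by 1.84 ± 0.35 (adjusted p = 4.01e-04), from a signal of 7.97 ± 10.1 to 67.0 ± 20.7 (SD, n = 3), and LBD16 rose by 1.58 ± 0.28; of the 4 lateral root initiation genes 2 rose, and 3 when adjusted over the list alone. AT1G64405 rose by 4.07 ± 0.35 and AT3G60650 by 4.22 ± 0.45. AT2G41810 fell by 4.31 ± 0.27, AT2G43890 by 3.71 ± 0.32 and GSTU28 by 3.34 ± 0.36. Fits limited to the 6 pericycle arrays called 387 genes, and fits with array weights 642.

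In the epidermis 1191 genes were called, 555 higher and 636 lower (608 and 596 with centring on the 75th percentile). The largest rises were again those of GH3.3, by 6.29 ± 0.23, IAA29, by 6.00 ± 0.29, GH3.5, by 5.97 ± 0.21, and IAA30, by 5.06 ± 0.27. AT2G41810 fell by 5.40 ± 0.27, AT1G33700, a predicted glucosylceramidase, by 4.39 ± 0.32, and AT5G17820 by 4.16 ± 0.55. The root hair expansins fell more than 4-fold: EXPA18 went from a signal of 314 ± 51.6 to 4.94 ± 3.23 (SD, n = 3; adjusted p = 1.39e-10), and EXPA7 fell by 2.62 ± 0.34. Of the 3 tested root hair genes 2 fell, and 3 when adjusted over the list alone. The list of expansins and xyloglucan endotransglucosylases was lower than other genes (camera adjusted p = 0.00525, but adjusted p = 0.0753 with an estimated correlation), with 3 of 10 members that fell and none that rose, and the same counts when adjusted over the list alone.

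In the columella 661 genes were called, 350 higher and 311 lower (309 and 321 with quantile normalization, 313 and 351 with centring on the 75th percentile). GH3.3 rose by 6.35 ± 0.23, IAA29 by 5.90 ± 0.29, AT2G17680 by 4.51 ± 0.39 and AT3G28510, an AAA-type ATPase gene, by 4.17 ± 0.37. RTE1 rose by 1.95 ± 0.33. AT2G41810, AT2G43890 and AT1G33700 fell by 5.33 ± 0.27, 3.83 ± 0.32 and 3.52 ± 0.32, and EXPA18 and EXPA7 fell by 3.18 ± 0.36 and 2.20 ± 0.34. The list of expansins and xyloglucan endotransglucosylases was again lower than other genes (camera adjusted p = 0.00380, but adjusted p = 0.0668 with an estimated correlation), with 3 of 10 members that fell; adjusted over the list alone, 3 fell and 1 rose.

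**Figure D2:**
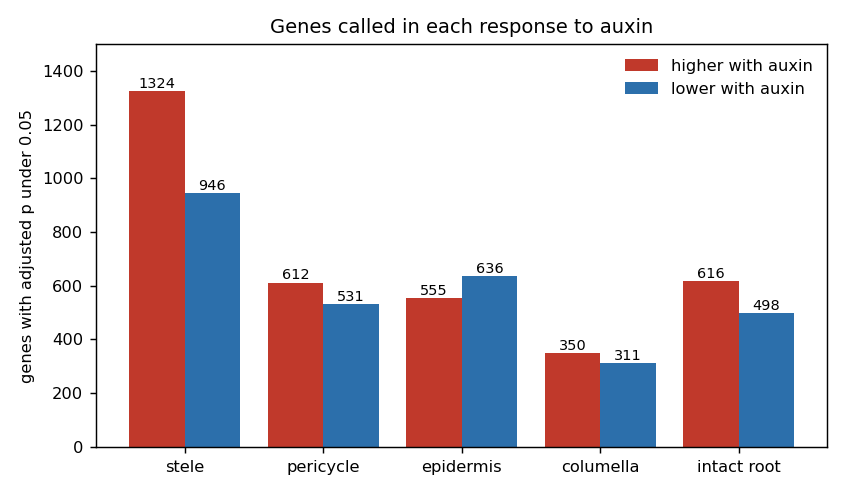
Number of genes called higher and lower with auxin in each sorted tissue and in intact roots (adjusted p under 0.05). The stele had the most, 1324 and 946, and the columella the fewest, 350 and 311. In fits limited to the arrays of the groups compared, the pericycle had the fewest, 387 in all.

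Most calls were made in a single sorted tissue: 1292 genes were higher in exactly 1 tissue, 375 in 2, 129 in 3 and 103 in all 4, and 796, 312, 180 and 116 were lower. A call in a single tissue does not show that the response differed from that of the other tissues. Higher in all 4 sorted tissues were 103 genes, of which 49 were also higher in intact roots, and lower in all 4 were 116, of which 45 were also lower in intact roots. GH3.3, GH3.5, GH3.1 (AT2G14960), IAA29, IAA30, HAT2 and LBD16 were among the former, and AT2G41810, AT2G43890, GSTU28, EXPA18 and EXPB1 among the latter. The epidermis and columella responses resembled each other most: 243 genes rose in both, where independent lists would share 20.8, 257 fell in both, where 21.2 would be shared, and none moved in opposite directions. Their changes correlated at r = 0.753 over the 9323 genes, against 0.565 to 0.634 for the other pairs of sorted tissues (across genes, which are not independent replicates). Opposite calls between any sorted tissues were few, 25 genes out of 3278 called in at least 1 tissue.

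Which responses differ between tissues was asked with the F-test, which called 241 genes. AT1G33700 had the smallest p (adjusted p = 8.49e-09): it fell by 4.39 in the epidermis and 3.52 in the columella, with changes of −0.71 in the stele and 0.35 in the pericycle that did not pass. GH9C1 (AT1G48930), an endoglucanase gene, rose by 1.02 in the stele and fell by 2.60 in the epidermis and 1.58 in the columella (adjusted p = 7.58e-06). XTH33 (AT1G10550), a xyloglucan endotransglucosylase gene, fell by 2.83 in the epidermis, 2.62 more than in the mean of the other tissues (adjusted p = 5.17e-07). Its mean signal percentile in mock samples was 72.0 in the epidermis and 51.4 in the columella. In the mock stele and pericycle it was 33.2 and 30.1, so the gene had little room to fall there. GTR1 (AT3G47960), which encodes a glucosinolate transporter, fell by 1.98 in the stele and 1.43 in the epidermis, and its change in the pericycle, 0.22, lay 1.60 above the mean of the other tissues (adjusted p = 7.39e-06). AT1G28160 fell by 3.43 in the stele, its tissue of highest mock level, with changes between −0.73 and −0.22 in the other tissues that did not pass (adjusted p = 9.20e-05). AT1G54050 and AT1G79910 rose more in the stele than in the mean of the other tissues, by 2.23 and 2.15. Both had a lower mock level in the stele than in the other sorted tissues. For AT1G54050 the mean signal percentile rose from 93.3 to 99.2 in the stele and was 98.3 to 99.1 in the other mock tissues. For AT1G79910 it rose from 36.8 to 68.6, and the other mock tissues had 53.6 to 66.7. Auxin targets common to all tissues also differed in size: GH3.3 rose by 7.74 in the stele and 7.52 in the pericycle, against 6.29 in the epidermis and 6.35 in the columella (adjusted p = 0.00436), and GH3.5 rose 1.37 more in the epidermis than in the mean of the other tissues (adjusted p = 4.76e-05).

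Some AAA-type ATPase genes were among those with different responses. AT3G28580, an AAA-type ATPase gene, rose by 3.09 ± 0.35 in the epidermis and 3.64 ± 0.35 in the columella, with changes of −0.54 and 0.48 in the stele and pericycle that did not pass (adjusted p = 1.01e-06). Its mock signal was 1347 ± 353 in the pericycle and 28.6 ± 13.5 in the epidermis (SD, n = 3). AT3G28510 and AT5G17760 rose by 3.96 and 3.51 in the epidermis, against 0.57 and 0.86 in the stele, where only AT5G17760 was called. A list of 9 tested genes of this group was written after these values were seen. Of its 9 members, 5 were called lower in the stele response than in the mean of the other tissues, and 4 were called higher in the epidermis and in the columella, with 1 higher and 3 lower in the pericycle. In mock samples 4 members were higher and 1 lower in the stele, 4 were higher in the pericycle, 5 lower in the epidermis, and 4 lower and 1 higher in the columella. Because the list holds the genes that led to it, its camera tests are not used here. None of the 3 fixed lists that could be tested differed in its response between tissues with an estimated correlation. The number of genes called by the F-test depended on single arrays and on the model: it was 148 without stele auxin replicate 2, 135 with the intact roots left out of the fit, and 437 with array weights.

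**Figure D3:**
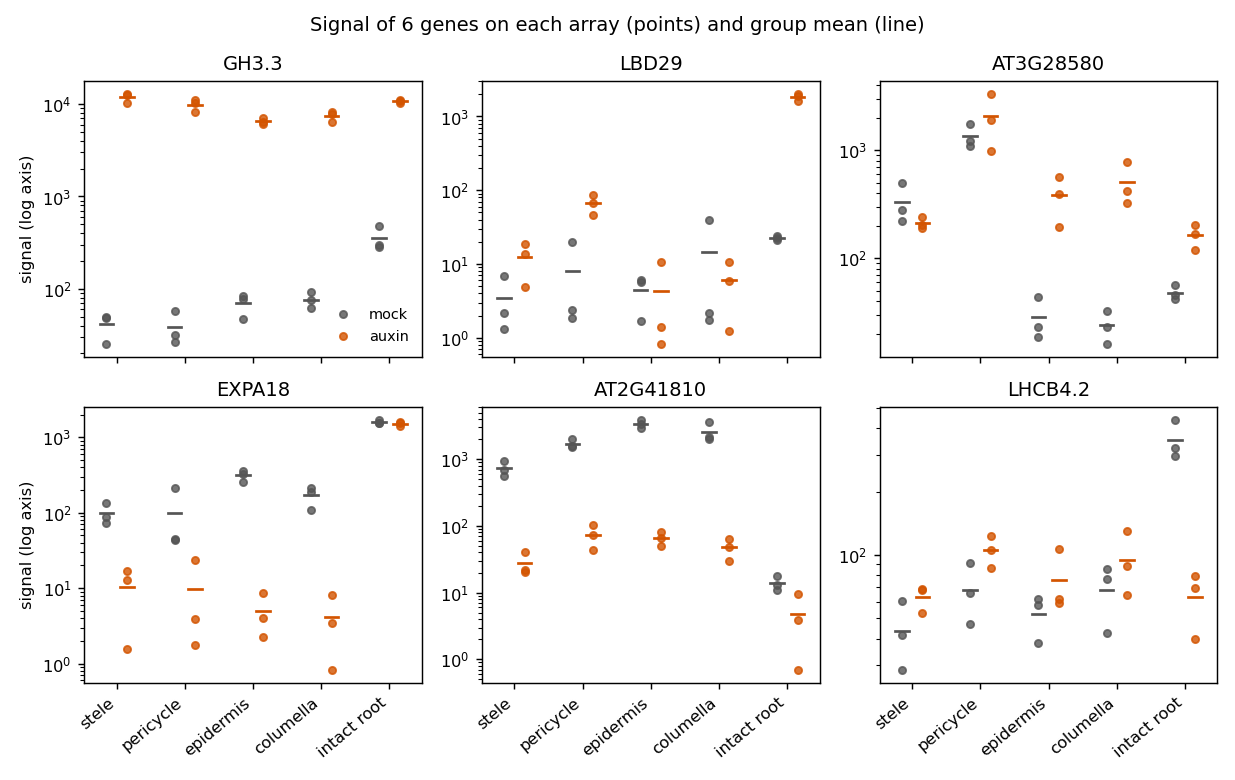
Signal (log axis) of GH3.3, LBD29, AT3G28580, EXPA18, AT2G41810 and LHCB4.2 on each mock and auxin array of the 5 sample types, with group means as lines. EXPA18 fell in sorted tissues, for example by 3.98 (log2) in the epidermis, but not by the test in intact roots, and LHCB4.2 fell by 2.24 in intact roots.

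The response of intact roots was measured without digestion or sorting. IAA29 rose by 6.71 ± 0.29 (adjusted p = 2.08e-19), GH3.1 by 5.73 ± 0.20, LBD29 by 5.60 ± 0.35, GH3.3 by 4.91 ± 0.23 and IAA30 by 4.74 ± 0.27. LBD29 went from a signal of 22.7 ± 1.44 to 1862 ± 202 (SD, n = 3), and PUCHI and LBD16 rose by 2.11 ± 0.35 and 1.69 ± 0.28, so that 3 of the 4 lateral root initiation genes rose, as many as when adjusted over the list alone. IAA18 (AT1G51950) rose by 2.07 ± 0.29. Of 6 Aux/IAA genes 3 rose, and 4 when adjusted over the list alone. Of the cell wall genes, EXPA4 rose by 2.96 ± 0.34 and EXPB1 fell by 1.76 ± 0.32; the list had 2 members up and 2 down, also when adjusted over the list alone, and was not called (adjusted p = 0.532). The largest falls were those of AT1G19900 (10.5-fold), AT3G62550, by 2.92 ± 0.42, and AT3G20015, by 2.71 ± 0.36, and the peroxidase gene AT3G01190 fell by 2.68 ± 0.36. In total 1114 genes were called, 616 higher and 498 lower; fits limited to the 6 intact-root arrays called 1887 genes and fits with array weights 2039.

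Light-harvesting genes and markers of the endodermis and cortex fell with auxin in intact roots. The light-harvesting gene LHCB4.2 (AT3G08940) fell by 2.24 ± 0.29 (adjusted p = 5.02e-07), LHCB4.1 (AT5G01530) was called lower at −0.93 ± 0.32, a call lost in 8 settings, 4 of them with 1 array left out, and the Calvin cycle gene PRK (AT1G32060) fell by 1.12 ± 0.27. LHCB4.1 and LHCB4.2, the light-harvesting genes tested, were also called lower when adjusted over the list alone. In a list of 10 photosynthesis genes, written after these values were seen, 4 fell, and 6 when adjusted over the list alone (camera adjusted p = 2.23e-05, but adjusted p = 0.143 with an estimated correlation). The endodermis receptor gene SGN3 (AT4G20140) fell by 1.28 ± 0.28 and the cortex marker C1 (AT1G09750) by 1.49 ± 0.35, both tested members of that list, as when adjusted over the list alone. UGT74D1 (AT2G31750), which encodes an auxin glucosyltransferase, fell by 1.51 ± 0.32.

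Whether intact roots and sorted cells respond alike was tested as the difference between the intact response and the average of the sorted tissues, which called 1034 genes, 491 with a higher and 543 with a lower response in intact roots (517 and 424 with quantile normalization). GH3.1 rose 4.36 ± 0.22 more in intact roots (adjusted p = 9.73e-17). Its mock signal was 24.8 ± 1.94 in intact roots and 239 ± 46.7 in the sorted stele (SD, n = 3). LBD29 rose 5.08 ± 0.39 more in intact roots. GH3.3 rose 2.06 ± 0.25 less there, and the change of AT3G26470 was −3.73 ± 0.35 relative to the sorted tissues. Both started from a higher mock level in intact roots. The mean signal percentile of GH3.3 was 77.8 in intact mock roots and 37.5 to 53.2 in sorted mock tissues. That of AT3G26470 was 89.5 and 22.5 to 44.3. With auxin, GH3.3 reached 99.97 in intact roots and 99.3 to 99.8 in sorted tissues, so its smaller rise was not a lower end level. Opposite directions were seen for AT1G67750, a predicted pectate lyase gene, which rose by 4.46 ± 0.33 in intact roots and fell by 1.71 ± 0.16 on average in sorted tissues, and for AT3G59850, which rose by 3.42 ± 0.25 and fell by 1.39 ± 0.13. The peroxidase gene AT2G18980 rose by 2.18 ± 0.33 in intact roots and fell in every sorted tissue. Of the 3 tested wound and jasmonate genes, WRKY53 (AT4G23810) rose by 1.79 ± 0.32 in intact roots. EXPA18 and EXPA7, lower in sorted cells, had changes of −0.09 and 0.26 in intact roots that did not pass, and the differences were called (adjusted p = 5.79e-06 and adjusted p = 1.55e-04). Of the 10 expansins and xyloglucan endotransglucosylases, 4 had a higher response in intact roots, also when adjusted over the list alone (camera adjusted p = 0.00300, but adjusted p = 0.0620 with an estimated correlation). Among the photosynthesis genes, 9 of 10 had a lower response in intact roots (camera adjusted p = 7.45e-09, and adjusted p = 0.0464 with an estimated correlation). The list was written after falls in intact roots were seen and holds the genes that led to it, so neither p-value counts as support. In the sorted tissues 9 of the 10 photosynthesis genes rose on average, with a mean change of 0.69 (camera adjusted p = 0.00289, but adjusted p = 0.258 with an estimated correlation), and both light-harvesting genes rose (LHCB4.2 not with quantile normalization). Several of these genes had low signal in sorted mock cells. In the mock stele the mean signal percentile was 6.68 for PSAE-1, 9.28 for SBPASE and 12.1 for PORB, against 56.4 for PRK. Rises of such dim genes were measured near the floor and do not show induction by auxin. In 64 genes a fall in a sorted tissue stood beside a rise in intact roots, and in 31 the reverse. Changes in intact roots correlated with those in the sorted tissues at r between 0.258 and 0.310 across genes. With array weights 1874 genes were called, and because sorted cells were exposed to auxin for longer, exposure and sorting are not separated in this difference.

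**Figure D4:**
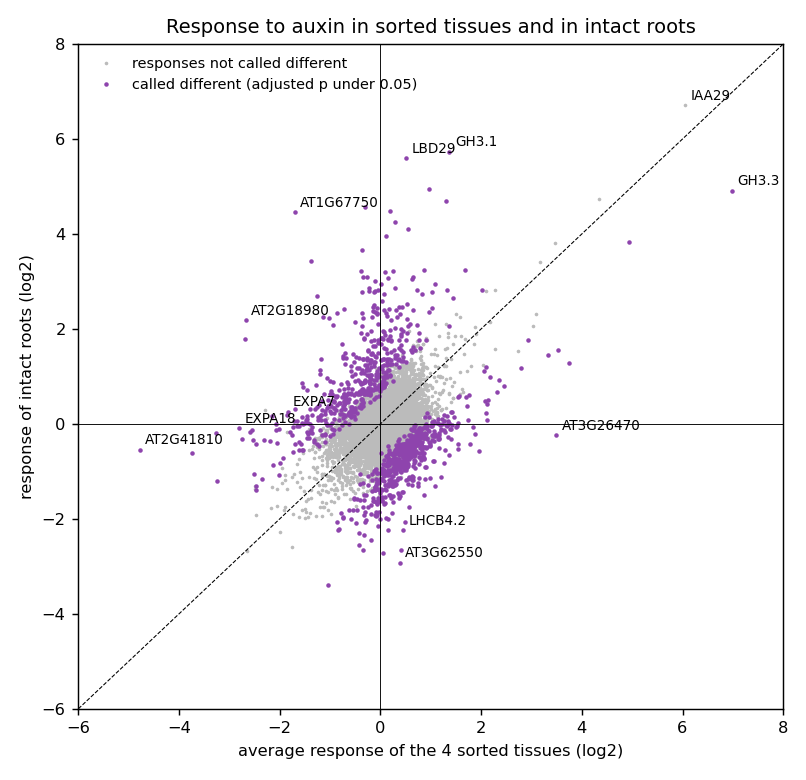
Response of intact roots (log2, vertical) against the average response of the 4 sorted tissues (log2, horizontal) for 9323 genes, with the genes whose responses were called different in purple. GH3.1 (5.73 and 1.37) and AT1G67750 (4.46 and −1.71) lie far from the dashed line of equal response.

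Mock-treated sorted tissues were compared with each other to see how their levels differed before auxin. The root cap polygalacturonase gene RCPG (AT1G65570) was 2.87 ± 0.25 higher in the columella than in the mean of the other tissues, and LZY3 (AT1G72490), a gene of gravity signalling, 1.70 ± 0.30 higher; of the 3 tested root cap and columella markers 2 were higher, and 3 when adjusted over the list alone. In the epidermis EXPA7 and GH9C1 were 1.47 ± 0.28 and 1.67 ± 0.27 higher. The pericycle had the largest single differences: AT1G67870 was 6.41 ± 0.31 higher there, BCAT4 (AT3G19710), a gene of methionine-derived glucosinolate synthesis, 4.78 ± 0.27 higher, and LBD16 2.07 ± 0.23 higher. MGL (AT1G64660), which encodes methionine gamma-lyase, was 10.6-fold higher in the stele, and of the 2 tested stele markers LHW (AT2G27230) was called, 1.02 ± 0.26 higher (not called without stele control replicate 3), while PHV (AT1G30490) did not pass over all genes; adjusted over the list alone both were higher. The epidermis marker TRY (AT5G53200) did not differ by the test, with 0.19 in the epidermis. The endodermis and cortex markers SGN3 and C1 were both called higher in the pericycle and both lower in the epidermis, also when adjusted over the list alone; neither pericycle call held without pericycle control replicate 2, and that of C1 in the epidermis was lost without epidermis control replicate 1. Of 5 GH3 genes 3 were higher in the columella, also when adjusted over the list alone (camera adjusted p = 0.00144, and adjusted p = 0.010 with an estimated correlation). The F-test called 3268 genes.

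Digestion and sorting were compared with intact tissue in the mock samples, where 5685 genes differed, 2818 higher and 2867 lower in sorted cells (2979 and 2616 with quantile normalization, 3249 and 2493 with centring on the 75th percentile), and 3131 by more than 2-fold. AT1G76640, also known as CML39, was 7.01 ± 0.16 higher in sorted cells (adjusted p = 5.41e-29), a size that depends on the pseudocount, since its signal in intact mock roots was 9.88 ± 7.45 (SD, n = 3), the small heat shock protein gene HSP17.6C (AT1G53540) 6.80 ± 0.29 higher, and the calmodulin-like gene CML37 (AT5G42380) 5.74 ± 0.20 higher. All 3 tested wound and jasmonate genes (CML37, ZAT10 and WRKY53) and both tested heat shock genes were higher in sorted cells, also when adjusted over the list alone; ZAT10 (AT1G27730) differed by 3.62 ± 0.20. AT2G41810, the named gene that fell most with auxin in sorted cells, was 5.92 ± 0.21 higher in sorted mock cells than in intact mock roots. Root hair genes were lower in sorted cells, XTH26 (AT4G28850) with −3.83 and EXPA18 with −3.36, 3 of 3 tested members, also when adjusted over the list alone. All 10 photosynthesis genes were lower (adjusted p = 4.17e-06, but adjusted p = 0.120 with an estimated correlation), the signal of RCA (AT2G39730), which encodes Rubisco activase, was 1143 ± 364 in intact roots and 23.9 ± 12.5 in the stele (SD, n = 3), and the osmotin-like gene OSM34 (AT4G11650) had a difference of −5.59. MCM7 was 1.80 ± 0.24 higher and the meristem gene JKD (AT5G03150) had a difference of −1.48 ± 0.27. Centring arrays on the 75th percentile moved the median difference of all genes by 0.13, and the directions given here are relative to the deposited scaling. Intact roots also hold tissues that were not sorted.

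Probe sets without a named gene also responded. Of 7183 such probe sets past the filter, 3137 (43.7%) were called for the average response of the sorted tissues, against 41.2% of named genes, and 5.28% against 2.59% for the response that differs between tissues. The largest rises among them were those of 262099_s_at, by 5.66 ± 0.15, and 254459_at, by 5.20 ± 0.16, and the largest falls those of 255591_at, by 5.07 ± 0.14, and 264567_s_at.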

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

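The tests of the root hair list and of green tissue, with all photosynthesis genes and without LHCB4.2, were chosen only after the result was seen. Results stand here because a response differed between sample types by a test of the difference, or because a signal appeared in data that the comparisons of named genes leave out. The first kind are the 241 genes whose auxin response differed among the 4 sorted tissues and the 1034 genes whose response differed between intact roots and the sorted tissues. The second kind are the 3137 probe sets without a named gene that were called for the average response of the sorted tissues; what these measure was not analysed here, and no explanation was tested.

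Other splits of the same arrays were used to ask whether chance could give counts as large. Of 100 splits, only 1, the real one, reached the real count for the average response (3838 genes, highest other split 719), for the response that differs among tissues once additive effects were removed (213, highest other 2), for intact against sorted responses after the same step (995, highest other 46), for differences between mock-treated tissues (3268, highest other 2114) and for mock-treated sorted against intact samples (5685, highest other 5108). This is the smallest share that 100 splits can give, so it argues against chance for these counts without excluding it. The 10 splits of 6 arrays behind each single response are too few for a share under 0.05. Only 1 split, the real one, reached the real count in the stele (2270, highest other 1), the pericycle (1143, highest other 25), the epidermis (1191, highest other 0), the columella (661, highest other 29) and intact roots (1114, highest other 0).

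Auxin lowered 254 genes on average in sorted tissues that it lowered less, or not at all, in intact roots; 61 of them rose in intact roots, 7 fell and 186 were not called. EXPA18, AT2G41810 and AT1G67750 are examples. A gene with low signal in intact mock roots has little room to fall there. AT2G41810 had a mean signal percentile of 23.3 in intact mock roots, against 95.4 for EXPA18 and 55.5 for AT1G67750. How many of the 254 genes lay so low was not counted. Under the less favourable of 2 other scalings 96.5% of the 254 genes kept both calls. These scalings moved the median of all genes, intact minus sorted response, by 0.067 and 0.011. Shifts so small make this a weak test of the deposited global scaling as the source. Digestion might have raised such genes before auxin lowered them again, but of genes chosen without the held-out mock replicate a median of 66.7% (63.2% in the lowest of 3 rotations, against 48.9% to 51.4% of all genes) were higher in sorted mock cells, between the shares set for and against this explanation, so for the whole group this and the explanations left open cannot be told apart. For the 3 tested root hair genes the median mock difference was −3.36 (log2, sorted minus intact). Sorted and intact samples also differ in tissue composition, so this cannot show whether digestion raised these genes within a tissue. The longer exposure of sorted cells to auxin and a difference between tissues stay open, untested.

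Of 10 photosynthesis genes, 4 fell with auxin in intact roots, LHCB4.2 and PRK among them, and 6 were not called; the list was not called with an estimated correlation (adjusted p = 0.143). The highest median change under 2 other scalings was −0.90. These scalings moved the median change of all genes in intact roots by 0.011 and −0.0083. With so small a shift the result could hardly have come out otherwise, so it does not decide on the deposited global scaling. Less green shoot tissue in the auxin-treated samples would lower all members, and alike only if the root itself expressed none of them. The 10 changes differ from one another (heterogeneity Q = 21.1, approximate chi-squared p = 0.0121), but this rests on LHCB4.2, without which Q is 2.97 and the shared change −0.90 ± 0.12; as the most deviating gene was taken out, the likeness of the other 9 is no evidence for less green tissue. Less green tissue and an effect of auxin in the root, untested, cannot be told apart for the whole list.

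Genes whose response differed among tissues tended to respond less, or to fall, where they were high without auxin, with r = −0.302 over 241 genes and 4 tissues, where simulated unchanged responses gave r = −0.178. The simulated responses were noise alone and were not chosen by the F-test, so the 2 values of r are not directly comparable. The covariances were −0.277 and, for simulated noise, −0.0562, with the same limit of selection. Mock arrays enter both the response and the mock level, and with responses and levels from separate mock replicates the correlation ran from −0.323 to 0.0325 in 3 rotations, so that a relation between the 2 quantities and chance values of the shared mock arrays cannot be told apart. The rotations chose 77 to 228 genes, and the highest value, 0.0325, came from the largest set. That rotation held out mock replicate 1, while the auxin arrays of that number stayed in. These arrays correlated with the mock arrays held out, at r = 0.375 in the epidermis and 0.253 in the columella. The levels and responses of that rotation were therefore not independent, which can raise its value. The other rotations gave −0.323 and −0.246. A signal near the top of the scale is argued against for most of these genes, since 9.13% of them had a group mean above the lowest 99th percentile of an array. The share over all tested genes was not computed. A difference between the tissues in which genes auxin can still raise stays open, untested.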

How the results depend on the processing

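The use of all probe sets and the fit without the 2 arrays of lowest weight were chosen after seeing the data. All counts stayed within 1.5 times the reported ones with quantile normalization, centring on the 75th percentile, eBayes without a trend, the mean over a gene's probe sets, and without the 2 arrays of lowest weight. Of 509 values of named genes, 389 kept their call in every setting that followed them (476 values with the stricter filter, 470 with only the arrays of the groups compared, none with all probe sets); over 13990 values 627 calls were lost and none changed sign. Signal over background limits genes with low signal, whose fold changes depend on the pseudocount.

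With all probe sets, where more were tested, 4372 were called in the stele, 2326 in the pericycle, 2381 in the epidermis, 1369 in the columella, 2327 in intact roots, 7177 for the average response, 621 for the tissue-dependent response, 2114 for intact against sorted responses, 6252 between mock tissues and 10618 between mock sorted and intact samples. With only the arrays of the groups compared, 387 genes were called in the pericycle, 1887 in intact roots and 135 for the tissue-dependent response, and intact against sorted responses have no separate value, as all arrays enter. Array weights gave 642 in the pericycle, 2039 in intact roots, 437 for the tissue-dependent response and 1874 for intact against sorted responses. The tissue-dependent response also gave 159 genes with a pseudocount of 1, 427 with a pseudocount of 64 and 146 without moderation. With a stricter filter 10 gene list tests passed in place of 19, and no filter gave a median correlation between tissues of 0.516 in place of 0.588. Apart from the use of all probe sets, the cause was not tested.

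Leaving out 1 array gave 1448 to 1927 genes in the stele, 804 to 968 in the pericycle, 806 to 1262 in the epidermis, 465 to 554 in the columella, 775 to 911 in intact roots, 3504 to 3924 for the average, 148 to 330 for the tissue-dependent response, 714 to 1099 for intact against sorted responses, 2721 to 3247 between mock tissues, 4975 to 5707 between mock sorted and intact samples, and 17 to 21 list tests. Array labels share only a number. With it as a replicate block the counts were 2652 in the stele, 1440 in the pericycle, 1479 in the epidermis, 841 in the columella, 1337 in intact roots, 4112 for the average, 404 for the tissue-dependent response, 1289 for intact against sorted responses, 3426 between mock tissues and 5747 between mock sorted and intact samples. Mock and auxin arrays of a tissue with the same number correlated with r between −0.011 and 0.375 over 15 pairs, 6 of them over 0.1, and 19 of 30 arrays correlated best with their own number.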

Other observations

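The families below and their members were chosen after their values were seen, and the tests of families were planned only then. Of 19 tested TBL genes (trichome birefringence-like), whose products act on cell wall polysaccharide acetylation, 9 fell and 2 rose on average in sorted tissues, and 10 fell and 2 rose when adjusted over the list alone, with TBL41 (AT3G14850) at −1.61, TBL25 (AT1G01430) at −1.16 and TBL37 (AT2G34070) at −0.92, while TBL36 (AT3G54260) rose by 0.72. In intact roots 7 fell and 1 rose, with TBL38 (AT1G29050) at −1.59 and TBL36 at 2.08. The family test gave adjusted p = 0.0203 on average and adjusted p = 0.0194 in intact roots, but adjusted p = 0.386 in both with an estimated correlation. Of 9 GSTU glutathione S-transferase genes, 6 fell and 3 rose on average, with GSTU28 at −3.24, GSTU26 (AT1G17190) at −1.76 and GSTU27 (AT3G43800) at −0.88, and with GSTU16 (AT1G59700) at 0.77 (adjusted p = 0.0448, but adjusted p = 0.449 with an estimated correlation).

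Ribosomal protein genes with the symbol stem RPS, 8 of 9 of them carried by the plastid genome, were all called higher on average in sorted tissues, also when adjusted over the list alone, with rps15 at 0.78, rps4 at 0.69 and rps18 at 0.68 (adjusted p = 0.0416, but adjusted p = 0.628 with an estimated correlation). In mock samples 8 of the 9 were lower in the epidermis than in the other sorted tissues (adjusted p = 7.5e-05, but adjusted p = 0.424 with an estimated correlation). No explanation for these family values was tested.

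Neighbouring genes responded to auxin together. Over 3511 pairs of genes next to each other on a chromosome, average responses in sorted tissues correlated with r = 0.224, above all of 1000 shuffled orders (−0.056 to 0.050); across genes, which are not independent replicates. Where both genes of a pair were called, 475 of 695 pairs (68.3%) moved the same way, against 52.2% by chance, such as AT4G35200 and AT4G35210 (3.09 and 3.04), AT1G60000 and AT1G60010 (2.28 and 3.53) and AT2G43880 and AT2G43890 (−1.92 and −3.74). Without the 47 pairs that held a doubtful probe set, r was 0.217 over 3464 pairs. Leaving out so few pairs could hardly move r. Pairs were doubtful by the name of a probe set or by signals that followed each other closely within groups. This can miss probe sets that match a similar neighbour in part, so probe sets that match several genes are not excluded as the source. The hypothesis that neighbours share their auxin response passed its test, and whether shared regulation, a common origin by duplication or another cause lies behind it was not tested.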
